A study of Mus musculus with 18 samples.

How the data were processed

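RNA from 18 cultures of FC-1801 cells, 3 per group in 6 groups, was hybridised to 1-colour arrays with 22690 mouse probe sets, after extraction with Trizol and biotin labelling, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which call the replicates biological. Whether these were separate infections is not stated, so p-values measure the spread between these cultures. The deposited values were the authors' intensity per probe set on a linear scale. The software and normalization behind them are not given in the sources used here. The 2% trimmed mean was 500.1 to 500.2 on every array, so the arrays had been scaled to 1 level, while array medians lay between 130.7 and 173.5, 0.41 apart on the log2 scale. Arrays give no counts, and the number of arrays limits the precision.

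Because the medians differed by more than 0.1 on the log2 scale, the arrays were quantile normalized. Values under 16 were then set to 16, which held for 16.9% to 19.8% of the probe sets of an array before normalization, and log2 was taken. A group whose 3 arrays all lay at this floor has only a bound, and its fold is written as at least that size. The platform annotation gave 20380 probe sets 1 gene symbol, 691 several and 1555 none, and 64 were array controls. Symbols were updated through Entrez identifiers, which matched 12369 of 12393 genes. Each gene was read by its probe set of highest mean over all arrays. A probe set whose identifier ends in s_at or x_at can also read other transcripts.

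Tests used R 4.3.3 and limma 3.58.1. One fit with 6 group means over all 18 arrays (lmFit, then eBayes) gave two-sided moderated tests of 9 group contrasts and of the interaction. The interaction is the difference of combined minus DCAF1 shRNA cells and Merlin minus control shRNA cells. Genes past a Benjamini-Hochberg adjusted p of 0.05 within a contrast were called changed. Of 31 gene lists with 676 genes fixed before the data were examined, 603 genes were measured. Lists were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over the 31 lists of a contrast. Most camera calls were not held with an estimated correlation, and that adjusted p is given beside them. Among markers of other cell types, fixed among the lists for fibroblasts, neurons, immune cells, endothelial and mural cells, and melanocytes and epithelia, no list was called in any contrast.

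Genes were named by a rule fixed before the data were examined. It takes Nf2 and Dcaf1, the 8 genes that rose most and the 8 that fell most in contrasts against control shRNA and in Merlin against Merlin-L64P, and 5 and 5 elsewhere. These had to pass the threshold with all arrays of a group on one side of all arrays of the other, which chance gives for 10% of genes in 3 against 3. For the interaction only the threshold applied. Up to 4 passing members of each list could also be named. For genes shared by Merlin and DCAF1 shRNA the order was by the smaller of the 2 changes. Chance sharing was simulated with 100 draws of unchanged groups against shared control arrays. In each draw the control arrays were simulated too, from the control shRNA means and the spread of each gene.

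The procedure was tested on simulated data made from the means and spread of these 12393 genes. For Merlin against control shRNA, 50 genes at each size were changed, and 28.0% were recovered at 1.25-fold, 50.0% at 1.5-fold, 84.0% at 2-fold and 98.0% at 4-fold, with 9 false calls. For the interaction the shares were 12.0%, 42.0%, 76.0% and 92.0%, with 6 false calls. These values hold where few genes change. In the data many more passed, 4997 for Merlin and 3734 for the interaction, which makes the adjusted threshold less strict. The shares and false calls therefore do not carry over to the real comparisons. Alternatives were values as deposited, arrays centred on their medians, a floor of 64, no lowest 25% of genes, the mean of all probe sets or each probe set on its own, only the arrays compared, trended and robust variances, array weights, stricter thresholds, another control group, the replicate number as a block, and leaving out single arrays. Figures were drawn with matplotlib 3.10.9.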

Results

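Gene expression was measured in FC-1801 cells, a mouse Schwann cell line that lacks Merlin, the tumour suppressor protein encoded by Nf2. The cells came from mouse embryos with floxed Nf2 alleles, were treated with adenoviral Cre and were immortalised in culture. The 18 arrays fell into 6 groups of 3 cultures. Parental cells were uninfected, and the other 5 groups carried lentiviral vectors for a control shRNA, wild type Merlin, the mutant Merlin-L64P, an shRNA against DCAF1, or wild type Merlin together with the DCAF1 shRNA. DCAF1 is a substrate receptor of the ubiquitin ligase CRL4. The design asks whether Merlin acts on gene expression by inhibiting that ligase, by setting the Merlin program beside that of the DCAF1 shRNA. Each array gave 1 signal for each of 22690 probe sets, and 12393 genes were tested. Array medians lay between 130.7 and 173.5 signal units before normalization. Arrays of 1 group correlated at r = 0.990 to 0.993 across probe sets, and arrays of different groups at r = 0.945 to 0.992. Below, values with ± are log2 fold changes with their standard error, from 3 arrays a side, and adjusted p is from limma.

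The targeted genes were read first, in a fit of every probe set, whose adjusted p differs slightly from the fit of 1 probe set per gene used further on. Of 4 Nf2 probe sets 1, that of lowest mean signal, was higher in the Merlin cells than in the control shRNA cells, by 1.31 ± 0.10 (2.48-fold, adjusted p = 4.96e-07). It was also higher in the cells with both vectors, by 0.98 ± 0.10 (adjusted p = 8.06e-06). In the cells labelled Merlin-L64P the difference was 0.19 ± 0.10 (adjusted p = 0.184), so no Nf2 excess over control shRNA was detected there, and these arrays are called "labelled Merlin-L64P" for that reason. Against parental cells the same probe set was higher in them by 0.68 ± 0.10 (adjusted p = 9.44e-05), but it was also higher in control shRNA cells by 0.50 ± 0.10 (adjusted p = 0.0016), and in Merlin cells by 1.81 ± 0.10 (adjusted p = 6.58e-09). Its log2 signal was 5.55 ± 0.05 (SD, n = 3) in parental, 6.05 ± 0.14 in control shRNA, 7.36 ± 0.12 in Merlin, 6.24 ± 0.14 in Merlin-L64P, 5.28 ± 0.17 in DCAF1 shRNA and 7.03 ± 0.13 in combined cells. The brightest Nf2 probe set, which stands for the gene in the counts below, was −0.23 ± 0.13 in Merlin cells against control shRNA (adjusted p = 0.181) and fell in DCAF1 shRNA cells by 0.71 on the log2 scale (adjusted p = 0.000562). The remaining Nf2 probe sets fell in Merlin cells, the brighter by 0.58 (adjusted p = 0.00168) and the dimmer by 0.72 (adjusted p = 0.00175) on the log2 scale. Which part of the transcript each probe set reads is not given in the sources used here. Dcaf1, read by the brighter of its probe sets, was lower in the DCAF1 shRNA cells than in control shRNA cells by a small amount, −0.20 ± 0.06 (1.15-fold, adjusted p = 0.0135). It was lower in the combined cells than in Merlin cells, −0.35 ± 0.06 (adjusted p = 0.0213), and higher in the arrays labelled Merlin-L64P than in control shRNA, 0.29 ± 0.06 (adjusted p = 0.000856). The dimmer Dcaf1 probe set differed by 0.13 ± 0.21 between DCAF1 shRNA and control shRNA (adjusted p = 0.734). In the fit of 1 probe set per gene, the Dcaf1 call in DCAF1 shRNA cells was lost against parental cells (−0.06, adjusted p = 0.441), with the mean of both probe sets (−0.03, adjusted p = 0.935) and with arrays centred on their medians (−0.11, adjusted p = 0.0704). It was also lost in 3 of 6 fits without 1 array, those without DCAF1 shRNA replicate 3 (adjusted p = 0.0647), control shRNA replicate 2 (adjusted p = 0.0513) and control shRNA replicate 3 (adjusted p = 0.0548).

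**Figure D1:**
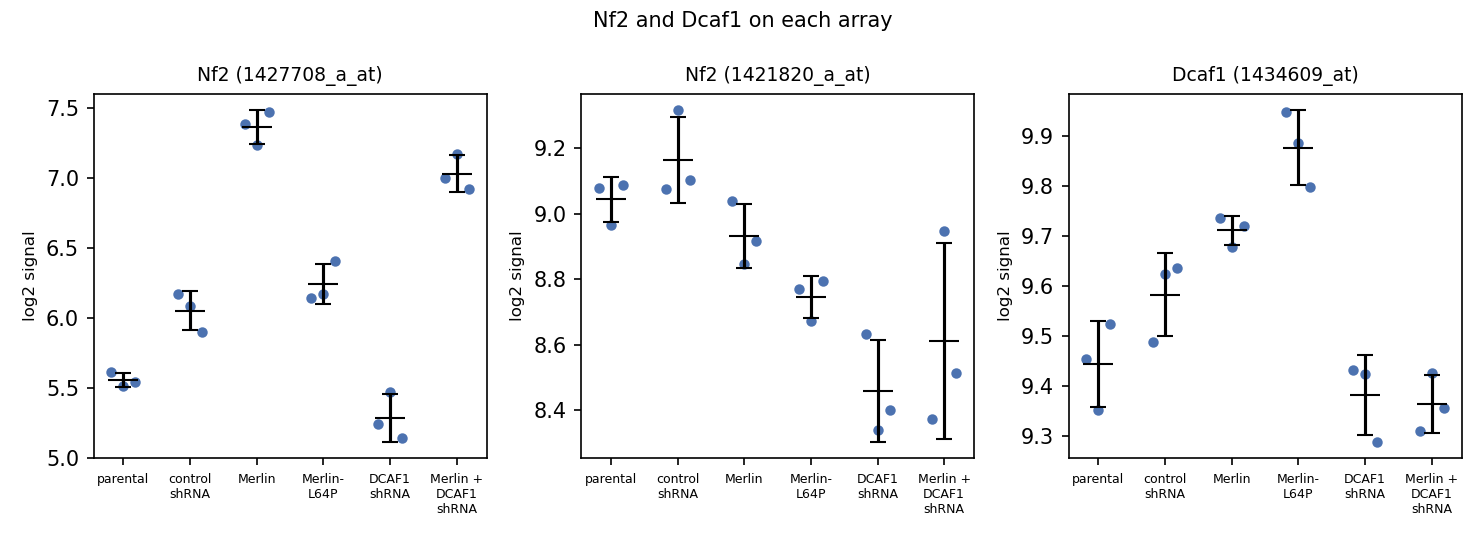
Log2 signal (vertical axis) of 2 Nf2 probe sets and 1 Dcaf1 probe set in the 6 groups (horizontal axis); points are arrays, and bars are the mean and SD of 3 arrays. The Nf2 probe set of lowest mean signal (left panel) averaged 7.36 in Merlin cells and 6.24 in the arrays labelled Merlin-L64P, and Dcaf1 averaged 9.58 in control shRNA and 9.38 in DCAF1 shRNA cells.

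Control shRNA cells were compared with uninfected parental cells. The groups differ by lentiviral infection with a control shRNA, and other differences between the cultures were not separated from it. Genes of cholesterol synthesis fell as a block: all 19 measured members were lower, with a median of −1.14, among them Lss (−2.08 ± 0.10), Idi1 (−1.83 ± 0.07), Nsdhl (−1.76 ± 0.07) and Fdft1 (−1.75 ± 0.06). This list was called by limma's camera at adjusted p = 1.04e-13, and at adjusted p = 0.00416 with an estimated correlation. Immune genes rose. Of 26 interferon response genes 14 rose and none fell, with Gbp2 at 2.14 ± 0.18 and Stat2 at 1.38 ± 0.11. Of 14 antigen presentation genes 9 rose and 1 fell, with the immunoproteasome subunits Psmb8 (3.55 ± 0.27) and Psmb9 (3.31 ± 0.15) and the peptide transporter Tap1 (1.72 ± 0.14). Chemokines were among the genes that rose most: Ccl5, at the floor in parental cells, was at least 19.8-fold higher, and Cxcl5 rose by 4.24 ± 0.16 (adjusted p = 4.22e-10). Of 21 p53 targets 13 rose and 1 fell, led by Trp53inp1 (4.31 ± 0.20), Fas (1.60 ± 0.26) and Mdm2 (1.12 ± 0.10). Of 33 mitosis genes 30 fell and none rose (median −0.76; Ncapg −1.22 ± 0.11, Plk1 −1.11 ± 0.10), and of 29 genes of DNA replication 20 fell (Cdc6 −1.20 ± 0.09). With an estimated correlation these calls were lost: adjusted p = 0.101 for interferon response, 0.0511 for antigen presentation, 0.117 for p53 targets, 0.111 for mitosis and 0.197 for replication, all adjusted p. YAP-TEAD targets (13 of 22 lower, 2 higher; Ankrd1 −2.37 ± 0.18), myelin genes (6 of 11 lower, 1 higher; Mal −1.99 ± 0.09), inflammatory cytokines (10 of 23 higher, 3 lower; Cxcl1 2.32 ± 0.11) and TGF-beta targets (9 of 18 higher, 1 lower; Junb 1.83 ± 0.12) were called too, with adjusted p = 0.0887, 0.0806, 0.108 and 0.0596 with an estimated correlation. The follistatin-related Fstl1 rose by 3.37 ± 0.14, while Afp (−3.54 ± 0.18), Myl9 (−3.35 ± 0.13), Olfm1 (−3.28 ± 0.34) and Tmem45a (−3.23 ± 0.12) fell, and Chst15 was at least 15.3-fold lower, at the floor in control shRNA cells. In all, 5483 genes changed, 2817 higher and 2666 lower. Some of these changes were shared by the other infected groups and some were not. The cholesterol list was lower than in parental cells in each of those groups. Cxcl5, against parental cells, was only 0.43 in Merlin, 0.13 in Merlin-L64P and 0.61 in combined cells. The control group therefore differed from the uninfected cells in many of the genes named below, and values against parental cells are given for genes and lists whose direction turned or whose call was lost, and for several genes whose size changed by over 1.5 times.

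Merlin cells were compared with control shRNA cells to read the program of wild type Merlin. The labels name no hairpin in the Merlin or Merlin-L64P cells, so an effect of the control shRNA is part of both comparisons. Cell division genes fell: 31 of 33 mitosis genes were lower (median −1.09), with the survivin gene Birc5 at −1.90 ± 0.13, the centromere histone Cenpa at −1.65 ± 0.07 and cyclin B2 (Ccnb2) at −1.57 ± 0.10. Of 29 replication genes 23 fell and 1 rose (median −0.56), with the ribonucleotide reductase subunit Rrm2 at −1.73 ± 0.08 and Pole at −1.64 ± 0.09. The thymidine kinase Tk1 fell by 3.11 on the log2 scale (adjusted p = 1.6e-09). Camera called mitosis at adjusted p = 5.12e-20 and replication at adjusted p = 9.3e-11, both lost with an estimated correlation (adjusted p = 0.0942 for each). Adhesion genes fell, 14 of 24 against 3 that rose, among them the integrin subunit Itga6 (−1.50 ± 0.04), and Itga4, at the floor in Merlin cells; adjusted p was 0.000916, or 0.0942 with an estimated correlation. Of 22 targets of the YAP-TEAD transcription factors 9 fell and 3 rose, with Fstl1 at −3.99 ± 0.14, Ccn3 at −2.54 ± 0.08 and Gadd45b at 2.06 ± 0.14 (adjusted p = 0.0113, and adjusted p = 0.0942 with an estimated correlation).

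The genes that rose most with Merlin against control shRNA were Egfl8 (3.69 ± 0.27, adjusted p = 1.7e-07), Phyhipl (3.40 ± 0.58), the extracellular superoxide dismutase Sod3 (3.13 ± 0.41), the clock output factor Dbp (2.69 ± 0.13), the transcription factor Snai2 (2.63 ± 0.25), Zfp119a (2.62 ± 0.26) and the insulin receptor substrate Irs2 (2.47 ± 0.20). Avil was at least 6.88-fold higher, at the floor in control shRNA cells. The sialomucin Cd34 fell most against control shRNA, by 4.05 on the log2 scale (adjusted p = 8.69e-11), followed by Fstl1, Cxcl5 (−3.81 ± 0.16), the caveolin Cav1 (−3.26 ± 0.14), Cdk18 (−3.25 ± 0.08) and Psrc1 (−2.75 ± 0.20), and Scara5 was at least 11.9-fold lower. Of 23 genes of the unfolded protein and amino acid response 14 rose and 3 fell, with Atf3 at 1.66 ± 0.06 and Xbp1 at 1.14 ± 0.07 (adjusted p = 0.00364, and adjusted p = 0.163 with an estimated correlation). Of 19 cholesterol genes 11 rose and 2 fell (Sc5d 0.83 ± 0.06, Cyp51 0.81 ± 0.04; adjusted p = 0.0097, and adjusted p = 0.163 with an estimated correlation). Of 21 p53 targets 8 fell and 4 rose; the members that fell most were Gtse1 (−2.12 ± 0.18) and Ckap2 (−1.83 ± 0.07), which act in mitosis (adjusted p = 0.017, and adjusted p = 0.34 with an estimated correlation). Of 19 ribosomal protein genes 10 fell by small amounts (Rpl14 −0.53 ± 0.10; adjusted p = 0.0153, adjusted p = 0.0942 with an estimated correlation), and with each array centred on its median the list turned direction (adjusted p = 0.488). Adjusted over the list alone, 31 mitosis, 24 replication and 14 adhesion genes fell. In all, 4997 genes changed, 2706 higher and 2291 lower. The balance depends on the scaling, with 2369 higher and 2614 lower in the values as deposited. Against parental cells the cholesterol list was lower, not higher (adjusted p = 6.66e-09), the p53 list turned direction (adjusted p = 0.821), and genes turned too, with Cyp51 at −0.60 and Sc5d at −0.30, Cxcl5 at 0.43 and Afp, which had risen by 1.99 ± 0.18 against control shRNA, at −1.54. The unfolded protein (adjusted p = 0.136) and ribosomal protein (adjusted p = 0.153) lists lost their call there. The order of genes differed as well. Cd34 was −1.32, Fstl1 −0.63, Psrc1 −1.40, Itga6 −0.57, Egfl8 1.02 and Snai2 1.04 against parental cells, while Cdk18 was −5.71, Irs2 4.35 and Phyhipl 4.07.

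DCAF1 shRNA cells were compared with control shRNA cells to read the effect of the DCAF1 shRNA. The heat shock protein gene Hspa1a rose most, by 4.33 ± 0.30 (20.1-fold, adjusted p = 1.73e-07), followed by the cystine transporter Slc7a11 with 3.77 ± 0.20, and the prostaglandin synthase Ptgs2 (3.35 ± 0.18), the glutathione transferase Gsta4 (2.98 ± 0.15) and the heme oxygenase Hmox1 (2.55 ± 0.13) rose too. The Hspa1a probe set may not tell this gene from its near-identical neighbour Hspa1b. Of 23 genes of the unfolded protein and amino acid response 19 rose and 1 fell (median 0.89), with Chac1 at 2.38 ± 0.14, Dnajb9 at 1.81 ± 0.09 and Herpud1 at 1.77 ± 0.06. This list was called at adjusted p = 1.73e-09, and at adjusted p = 0.0401 with an estimated correlation. Of 14 targets of the oxidative stress factor Nrf2 10 rose and none fell, with Gclm at 1.74 ± 0.10 (adjusted p = 4.37e-07, and adjusted p = 0.117 with an estimated correlation). Slc7a11 belongs to both lists. Against parental cells these genes were higher too, but by less for several: Hspa1a by 2.62, Slc7a11 by 2.61, Ptgs2 by 2.09 and Gsta4 by 1.90. Chac1 was higher by only 0.50 there (adjusted p = 0.0103), since it averaged 9.27 in parental cells, 7.39 in control shRNA and 9.76 in DCAF1 shRNA cells.

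Schwann cell lineage genes fell in the DCAF1 shRNA cells, 11 of 18 with none that rose (median −0.60): the lineage transcription factor Pou3f1 (−2.42 ± 0.23), the neuregulin receptor Erbb3 (−1.48 ± 0.10), Cadm1 (−1.30 ± 0.06) and L1cam (−1.29 ± 0.13). The list had adjusted p = 9.94e-06, and adjusted p = 0.117 with an estimated correlation. Of 33 mitosis genes 23 fell and 2 rose (median −0.44; Ccnb2 −1.13 ± 0.10, Birc5 −1.12 ± 0.13; adjusted p = 4.37e-07, and adjusted p = 0.374 with an estimated correlation). Among 29 replication genes 9 rose and 11 fell, and the list was not called. Of 25 genes of oxidative phosphorylation 19 fell by small amounts (median −0.23; Ndufv1 −0.48 ± 0.08), with adjusted p = 3.41e-06, adjusted p = 0.319 with an estimated correlation, and adjusted p = 0.152 with each array centred on its median. Other genes that fell most were Cd34 (−2.93 ± 0.11), Dcxr (−2.78 ± 0.48), the immediate early factor Egr1 (−2.67 ± 0.14), the cold-inducible Cirbp (−2.52 ± 0.07), Psrc1 (−2.48 ± 0.20), Nek8 (−2.42 ± 0.20) and Itm2a (−2.42 ± 0.11). Afp (2.91 ± 0.18) and Ampd3 (2.63 ± 0.17) also rose, and Chst15 was at least 5.87-fold higher. Of 21 p53 targets 10 fell and 5 rose (Zmat3 −1.68 ± 0.10; adjusted p = 0.0144), of 24 adhesion genes 12 fell and 3 rose (Cdh13 −1.27 ± 0.30; adjusted p = 0.0307), and of 19 cholesterol genes 9 rose and 3 fell (Mvk −0.70 ± 0.17; adjusted p = 0.0144), each with adjusted p = 0.374 with an estimated correlation. Adjusted over the list alone, 19 unfolded protein response genes and 11 Nrf2 targets rose, and 12 Schwann lineage genes fell. In all, 4653 genes changed, 2334 higher and 2319 lower (2126 and 2484 in the values as deposited). Against parental cells the cholesterol list was lower (adjusted p = 1.05e-10), the p53 list turned direction (adjusted p = 0.584), and Afp (−0.62) and Chst15 (−1.38) were lower. Calls lost there were those of Cd34 (−0.20, adjusted p = 0.175), Dcxr (−1.14, adjusted p = 0.0693), Ndufv1 (−0.17, adjusted p = 0.118), Cdh13 (−0.02) and the adhesion list (adjusted p = 0.149). Egr1 (−1.51), Psrc1 (−1.14), Zmat3 (−0.74), Cadm1 (−0.47) and Itm2a (−0.44) were lower by less than against control shRNA, and Dnajb9 (2.91) was higher by more.

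**Figure D2:**
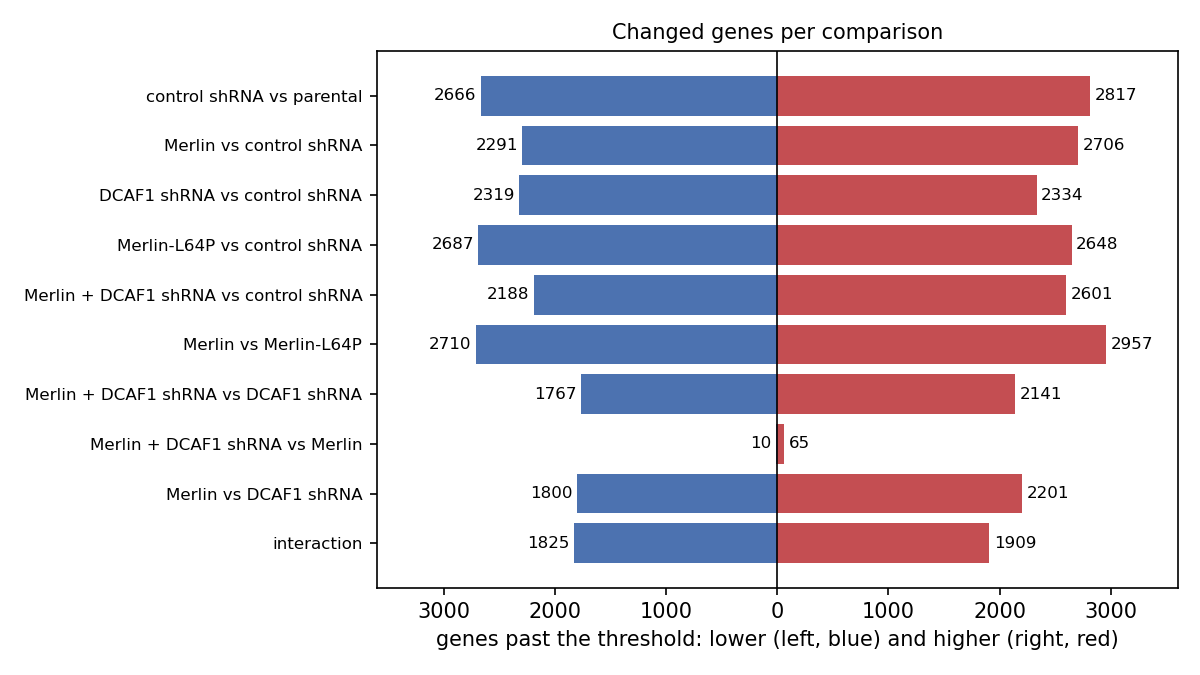
Number of genes past adjusted p of 0.05 (horizontal axis), lower to the left and higher to the right, in each of 10 comparisons (vertical axis). The combined cells differed from Merlin cells in 65 genes higher and 10 lower, while control shRNA differed from parental cells in 2817 higher and 2666 lower.

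The Merlin and DCAF1 shRNA programs were set side by side, which is the comparison the design names. Against control shRNA cells both lowered Cd34, Cirbp, Psrc1, Ly6g6d (−2.53 ± 0.38 with Merlin and −2.29 ± 0.38 with the DCAF1 shRNA) and the ETS factor Etv4 (at least 4.38-fold with Merlin, −2.10 ± 0.28 with the DCAF1 shRNA). Both raised Irs2 (2.47 and 2.14 ± 0.20), Afp (1.99 and 2.91 ± 0.18), Scg2 (at least 3.41-fold and at least 4.8-fold), Tert (at least 3.65-fold and at least 3.39-fold) and Frat2 (2.06 ± 0.71 with Merlin). Against parental cells part of this did not hold: Afp was lower with Merlin (−1.54) and with the DCAF1 shRNA (−0.62), Cd34 was −0.20 (adjusted p = 0.175) with the DCAF1 shRNA, Tert was 0.60 with Merlin and 0.50 (adjusted p = 0.0847) with the DCAF1 shRNA, Scg2 was 0.65 and 1.14, and Frat2 was 0.76 (adjusted p = 0.425) and 0.70 (adjusted p = 0.483). Of 3312 genes called in both comparisons 2982 went the same way, 1550 higher and 1432 lower, and 330 went opposite ways. Independent lists of these lengths would share 510 higher and 429 lower genes, and 100 simulations of unchanged groups against shared simulated controls shared at most 1. The simulations hold only noise between arrays, not a difference that all 3 control shRNA cultures have in common. Both comparisons use the same 3 control shRNA arrays, so part of the excess can come from them. Across genes, which are not independent replicates, the fold changes correlated at r = 0.62 (rho = 0.60), against a mean of r = 0.50 in the simulations; the covariance was 0.143 against a simulated 0.0177, a difference of 0.125. With no array in common, Merlin against Merlin-L64P correlated with DCAF1 shRNA against control shRNA at r = 0.30 (rho = 0.26), and 2286 of 3329 genes called in both went the same way. Merlin against parental cells gave r = 0.24 (rho = 0.23), and 2411 of 3548. The remaining such pair, Merlin against control shRNA with DCAF1 shRNA against parental cells, gave r = 0.42 (rho = 0.40), and 3020 of 3710. The cells labelled Merlin-L64P, against the same control shRNA arrays, also shared 2021 calls of one direction with DCAF1 shRNA cells, with 1135 opposite, and correlated at r = 0.24.

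**Figure D3:**
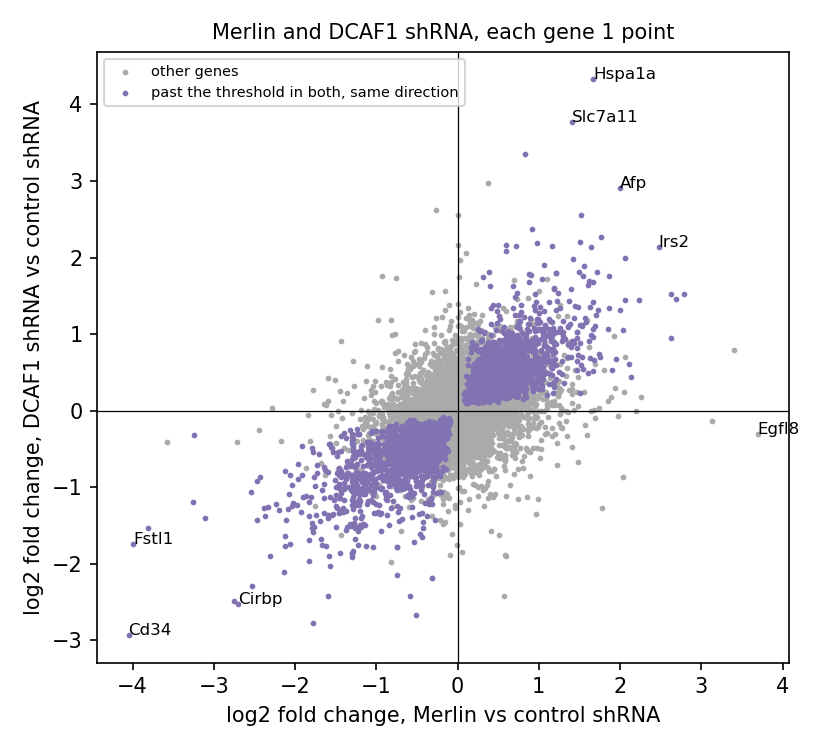
Log2 fold change of each gene in Merlin cells (horizontal axis) and in DCAF1 shRNA cells (vertical axis), both against control shRNA; violet points are the 2982 genes called in both in the same direction, and the others are grey. Cd34 and Cirbp lie low on both axes, and Hspa1a and Slc7a11 lie higher on the DCAF1 shRNA axis than on the Merlin axis.

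Merlin and DCAF1 shRNA cells were also tested directly against each other. Pou3f1 (2.99 ± 0.23), Erbb3 (1.52 ± 0.10), Sod3 (3.26 ± 0.41), Kcna1 (3.06 ± 0.47) and Capn6 (2.91 ± 0.16) were higher in Merlin cells, and Egfl8, at the floor in DCAF1 shRNA cells, was at least 15.9-fold higher. Cdk18 (−2.93 ± 0.08), Ampd3 (−2.90 ± 0.17), the cystathionase Cth (−2.69 ± 0.15) and Hspa1a (−2.66 ± 0.30) were lower, and Scara5 was at least 8.98-fold lower. YAP-TEAD targets were lower in Merlin cells, 16 of 22 against 1 higher, with Igfbp3 at −2.32 ± 0.07 and Fstl1 at −2.25 ± 0.14 (adjusted p = 2.38e-07, and adjusted p = 0.00483 with an estimated correlation). Replication (25 of 29) and mitosis (31 of 33) genes were lower in Merlin cells with none higher, with adjusted p = 0.0549 and adjusted p = 0.0746 with an estimated correlation. All 13 Nrf2 targets that passed, of 14, were lower in Merlin cells (adjusted p = 0.0581 with an estimated correlation), and 9 of 18 Schwann lineage genes were higher against 1 lower (adjusted p = 0.206 with an estimated correlation). In all, 4001 genes differed, 2201 higher and 1800 lower in Merlin cells.

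The arrays labelled Merlin-L64P were compared with control shRNA to set the mutant beside wild type Merlin. Replication genes rose, 25 of 29 with none that fell (median 0.83), among them Pola1 (1.67 ± 0.13), Cdc6 (1.37 ± 0.09) and Prim1 (1.20 ± 0.09). Genes of 3 other lists fell: 12 of 14 Nrf2 targets (Nqo1 −1.86 ± 0.15, Srxn1 −1.71 ± 0.08), 16 of 23 unfolded protein and amino acid response genes against 2 that rose (Trib3 −2.94 ± 0.14, Nupr1 −2.88 ± 0.19), and 16 of 19 cholesterol genes (Idi1 −1.79 ± 0.07, Msmo1 −1.48 ± 0.04). Camera called these at adjusted p = 1.51e-11, 1.18e-06, 6.37e-05 and 1.46e-07 in that order, and with an estimated correlation adjusted p was 0.116 for the first 3 and 0.0533 for cholesterol. Dbp rose most, by 3.98 ± 0.13 (15.8-fold, adjusted p = 9.51e-11), then the coactivator Ppargc1b (3.94 ± 0.35), the activin antagonist Fst (3.65 ± 0.19), Klf10 (3.12 ± 0.07), Gadd45b (2.85 ± 0.14), Pfkfb3 (2.84 ± 0.19) and Epha7 (2.71 ± 0.14), and Vegfc was at least 7.48-fold higher. The BMP-responsive Id3 fell most, by 4.26 on the log2 scale (adjusted p = 6.79e-12), then Cxcl5 (−4.11 ± 0.16), Moxd1 (−3.68 ± 0.11), the sphingosine phosphate receptor S1pr3 (−3.63 ± 0.15) and Serpina3n (−3.16 ± 0.35). Procr, Gsta4 (at least 8.87-fold) and Rnase4 (at least 8.12-fold) were at the floor. Against parental cells Cxcl5 differed by 0.13 (adjusted p = 0.595) and Cdc6 by 0.17 (adjusted p = 0.148). Ppargc1b was higher by only 1.26 there, while Idi1 (−3.62), Nqo1 (−3.04) and Msmo1 (−2.78) were lower by more than against control shRNA. In all, 5335 genes changed, 2648 higher and 2687 lower. These 3 arrays had a lower upper end of signal than the others, with maxima of 8650 to 10373 against 11114 to 14416.

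Wild type Merlin was then compared with the arrays labelled Merlin-L64P to read the difference between the wild type and mutant vectors. Replication genes were lower with wild type Merlin in 28 of 29 cases (median −1.32; Uhrf1 −2.53 ± 0.08, Rrm2 −2.39 ± 0.08), and mitosis genes in 31 of 33 (Birc5 −2.06 ± 0.13, Mki67 −1.97 ± 0.10). The replication call held at adjusted p = 0.0174 with an estimated correlation, and mitosis had adjusted p = 0.0821. YAP-TEAD targets were lower in 13 of 22 against 1 higher, with the angiomotin-like Amotl2 at −2.67 ± 0.11 (adjusted p = 0.0121 with an estimated correlation). Receptor tyrosine kinases and their ligands were lower in 15 of 34 against 4 higher, with Epha2 at −2.59 ± 0.37, Pdgfrb at −1.92 ± 0.07 and Pdgfra, in the opposite direction, at 2.72 ± 0.39 (adjusted p = 0.045 with an estimated correlation). Cholesterol genes were higher in 16 of 19 (Msmo1 1.95 ± 0.04, Hmgcs1 1.72 ± 0.09; adjusted p = 0.0121 with an estimated correlation) and unfolded protein and amino acid response genes in 18 of 23 against 2 lower (Slc7a11 3.01 ± 0.20; adjusted p = 0.0251 with an estimated correlation). Nrf2 targets were higher in 11 of 14 (adjusted p = 0.0821 with an estimated correlation). Moxd1 (5.81 ± 0.11, 56.3-fold, adjusted p = 1.38e-12), S1pr3 (3.96 ± 0.15), Phyhipl (3.93 ± 0.58), Cd24a (3.35 ± 0.14) and Afp (3.27 ± 0.18) were higher, as were, at the floor in Merlin-L64P, Egfl8 (at least 15.9-fold), Procr (at least 12.8-fold) and Gsta4 (at least 11.5-fold). Tk1 (−3.05 ± 0.13), Fst (−3.00 ± 0.19), Chtf18 (−2.94 ± 0.09), Prkcq (−2.93 ± 0.07) and Pde1a (−2.74 ± 0.14) were lower, and Hoxc4 was at least 8.15-fold lower. Oxidative phosphorylation was called lower, with 13 of 25 lower and 2 higher (Cyc1 −0.62 ± 0.06; adjusted p = 0.0151), but had adjusted p = 0.434 with an estimated correlation and turned direction with each array centred on its median (adjusted p = 0.919). In all, 5667 genes differed, 2957 higher and 2710 lower.

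**Figure D4:**
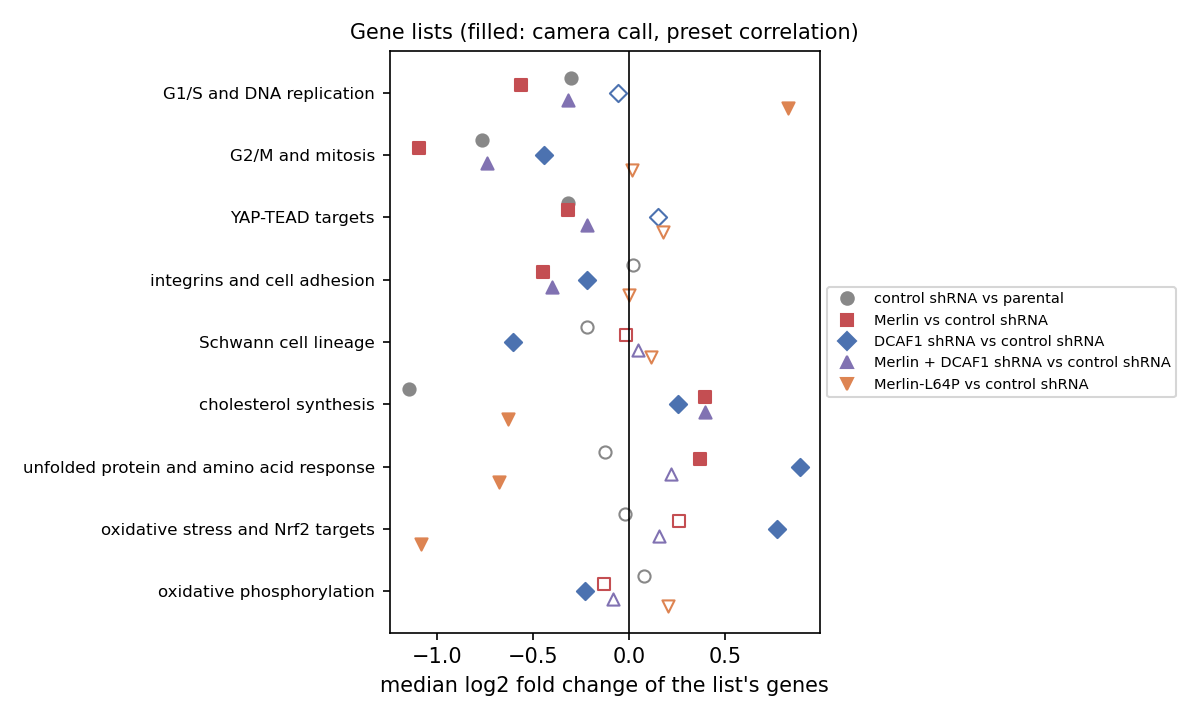
Median log2 fold change (horizontal axis) of the measured genes of 9 fixed lists (vertical axis) in 5 comparisons; filled markers are lists called by camera with the preset correlation. The unfolded protein and amino acid response lies at 0.89 in DCAF1 shRNA cells, and mitosis lies at −1.09 in Merlin cells.

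Cells with both vectors were compared with control shRNA cells. Egfl8 (3.80 ± 0.27), Phyhipl (3.28 ± 0.58), Dbp (2.90 ± 0.13), Sod3 (2.84 ± 0.41), Zfp119a (2.65 ± 0.26) and Ppargc1b (2.29 ± 0.35) rose, with Rhpn1 at least 5.9-fold and Avil at least 5.06-fold higher. Cd34 (−4.01 ± 0.11), Fstl1 (−3.86 ± 0.14), Cxcl5 (−3.63 ± 0.16), Epha2 (−2.78 ± 0.37), Cav1 (−2.66 ± 0.14), Psrc1 (−2.57 ± 0.20), Mme (−2.57 ± 0.25) and Cirbp (−2.45 ± 0.07) fell. Mitosis genes fell in 31 of 33 cases (median −0.74; Birc5 −1.47 ± 0.13) and replication genes in 19 of 29 (Tyms −1.59 ± 0.19), each with adjusted p = 0.13 with an estimated correlation. YAP-TEAD targets (9 of 22 lower, 3 higher; Ccn3 −2.04 ± 0.08), adhesion genes (14 of 24 lower, 4 higher; Cdh13 −2.10 ± 0.30) and ribosomal protein genes (9 of 19 lower; Rpl14 −0.57 ± 0.10) fell and cholesterol genes rose (11 of 19, 1 lower), with the same adjusted p = 0.13 with an estimated correlation, and 11 of 21 p53 targets fell (adjusted p = 0.171 with an estimated correlation). The unfolded protein and amino acid response list, with 12 members higher and 6 lower of 23, was not called, nor was Schwann lineage, with 5 higher and 3 lower of 18. In all, 4789 genes changed, 2601 higher and 2188 lower. Of 4247 genes called both here and in Merlin cells against the same arrays, 4246 went the same way, 2309 higher and 1937 lower, where independent lists would share 568 and 404. The fold changes correlated at r = 0.91 across genes. Both comparisons use the same 3 control shRNA arrays, and simulated unchanged groups gave a mean of r = 0.50, so part of this can come from them; the covariance was 0.215 against a simulated 0.0177. Against parental cells Ppargc1b (−0.39, adjusted p = 0.422) and Cxcl5 (0.61) turned direction, as did the cholesterol list (adjusted p = 8.6e-09), and the p53 (adjusted p = 0.904) and ribosomal protein (adjusted p = 0.134) lists lost their call. Egfl8 was 1.12, Cd34 −1.28, Fstl1 −0.50, Psrc1 −1.22 and Cdh13 −0.85 there, and Mme −4.19.

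Combined cells were compared with Merlin cells to read what the DCAF1 shRNA adds where Merlin is present. Few genes differed: 65 were higher and 10 lower, 75 in all, beside 1244 at an unadjusted p under 0.05. Cdk18 rose by 2.01 ± 0.08 (adjusted p = 3.35e-08), Prss29 by 1.14 ± 0.23, the imprinted gene Mest by 1.09 ± 0.12 and Tk1 by 1.05 ± 0.13, and Scara5 was at least 2.71-fold higher. Trpc7 (−1.86 ± 0.14), Npy1r (−0.87 ± 0.17), Pias4 (−0.48 ± 0.08) and Cyb5r1 (−0.42 ± 0.08) fell, and Bves was at least 2.24-fold lower. Mitosis genes were slightly higher, 6 of 33 over all genes and 23 adjusted over the list alone, with Kif2c at 0.54 ± 0.09 and Cdc20 at 0.43 ± 0.07 (median 0.29; adjusted p = 1.24e-26, and adjusted p = 0.0335 with an estimated correlation). The unfolded protein and amino acid response was slightly lower as a list (median −0.18, adjusted p = 0.0233 with an estimated correlation), with no member past the threshold over all genes and 10 lower adjusted over the list alone. Myelin genes were slightly higher as a list (median 0.20, adjusted p = 0.0233 with an estimated correlation), with no member past the threshold over all genes. The count fell to 1 with these 6 arrays alone, to 34 with arrays centred on their medians, and was, without 1 array, 26 (combined replicate 1), 42 (combined replicate 3), 43 (Merlin replicate 3) and 124 (Merlin replicate 2).

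Combined cells were compared with DCAF1 shRNA cells to read what Merlin adds where DCAF1 is targeted. Hspa1a (−3.55 ± 0.30, adjusted p = 1.36e-06), Ampd3 (−3.00 ± 0.17), Slc7a11 (−2.70 ± 0.20), Cth (−2.67 ± 0.15) and Gsta4 (−2.57 ± 0.15) were lower. Of 14 Nrf2 targets 12 fell (Gclm −1.71 ± 0.10, Hmox1 −1.49 ± 0.13), and of 23 unfolded protein and amino acid response genes 18 fell and 2 rose (Chac1 −2.10 ± 0.14, Trib3 −1.94 ± 0.14), each with adjusted p = 0.0474 with an estimated correlation. YAP-TEAD targets fell, 14 of 22 against 1 that rose, with Igfbp3 at −1.67 ± 0.07 (adjusted p = 0.00827 with an estimated correlation). Schwann lineage genes rose, 10 of 18 with none that fell, with Pou3f1 at 3.13 ± 0.23, Erbb3 at 1.72 ± 0.10 and Egr2, a myelination factor, at 1.27 ± 0.21 (adjusted p = 1.98e-05, and adjusted p = 0.0864 with an estimated correlation). Replication genes fell in 19 of 29 cases (Ccne2 −0.90 ± 0.12; adjusted p = 0.0864 with an estimated correlation), as did 18 of 33 mitosis genes (adjusted p = 0.256 with an estimated correlation). Kcna1 (3.25 ± 0.47), Sod3 (2.97 ± 0.41) and Capn6 (2.66 ± 0.16) rose, and Egfl8 was at least 17.1-fold higher. In all, 3908 genes changed, 2141 higher and 1767 lower.

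**Figure D5:**
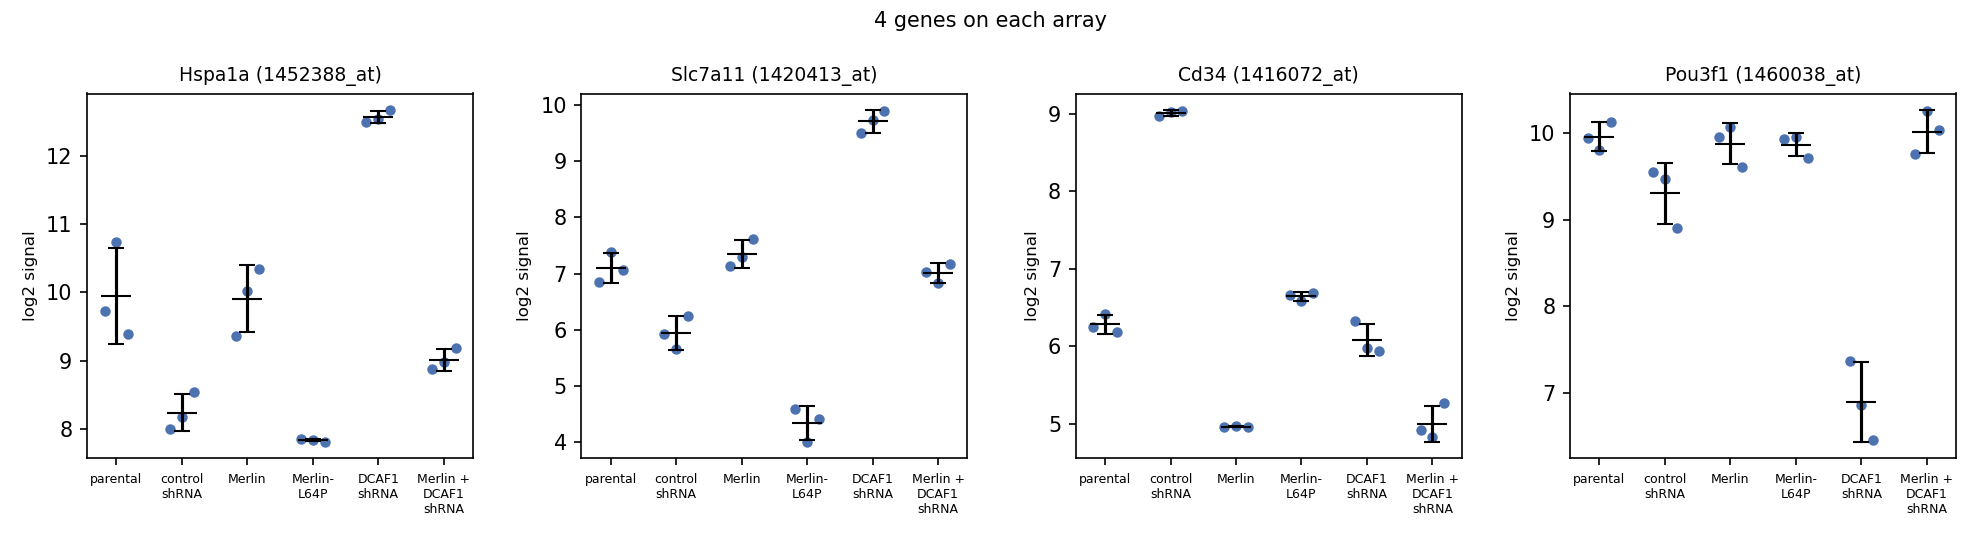
Log2 signal (vertical axis) of Hspa1a, Slc7a11, Cd34 and Pou3f1 in the 6 groups (horizontal axis); points are arrays, and bars are the mean and SD of 3 arrays. Hspa1a averaged 12.57 in DCAF1 shRNA and 9.02 in combined cells, and Cd34 averaged 9.01 in control shRNA against 6.28 in parental cells. Pou3f1 lay between 6.457 and 7.371 in DCAF1 shRNA cells and averaged 10.02 in combined cells.

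The interaction tested whether the Merlin effect differed with and without the DCAF1 shRNA. No group had Merlin with the control shRNA, so an effect of the control hairpin is part of this contrast and was not separated. The interaction also equals combined minus Merlin cells, less DCAF1 shRNA minus control shRNA cells. Combined and Merlin cells differed in only 75 genes, so it largely repeats the DCAF1 shRNA comparison with the sign turned. Ptgs2 had −3.32 here and 3.35 there, and Cd34 2.97 and −2.93. The most negative differences were those of Hspa1a (−5.22 ± 0.42, adjusted p = 1.59e-06), Slc7a11 (−4.11 ± 0.28), Ptgs2 (−3.32 ± 0.25), Afp (−3.08 ± 0.26) and Frat2 (−3.06 ± 1.00, adjusted p = 0.0338). Against control shRNA they rose with either vector alone, Hspa1a from 8.24 to 9.91 with Merlin and to 12.57 with the DCAF1 shRNA, and stood at 9.02 with both. Parental cells had Hspa1a at 9.95, near its Merlin level. Genes that fell with either vector and not further with both had positive differences: Ly6g6d (3.08 ± 0.54), Egr1 (2.97 ± 0.19), Cd34 (2.97 ± 0.16), Nek8 (2.90 ± 0.29) and Cirbp (2.77 ± 0.10). By lists, 18 of 23 unfolded protein and amino acid response genes had negative differences (adjusted p = 1.13e-11, and adjusted p = 0.02 with an estimated correlation). So did 10 of 14 Nrf2 targets (adjusted p = 0.105 with an estimated correlation), while 27 of 33 mitosis genes (adjusted p = 0.222 with an estimated correlation) and 11 of 18 Schwann lineage genes (adjusted p = 0.0925 with an estimated correlation) had positive ones. In all, 3734 genes passed, 1909 positive and 1825 negative. With parental cells as the baseline, 5081 passed, 2447 positive and 2634 negative. There, by tests of single genes and lists chosen after seeing the data, the differences were −3.51 for Hspa1a, −2.95 for Slc7a11, −2.07 for Ptgs2, 3.34 for Ly6g6d, 2.15 for Nek8, 2.01 for Cirbp and 1.81 for Egr1, all past the threshold. Those of Cd34 (0.24, adjusted p = 0.274) and Frat2 (−1.77, adjusted p = 0.196) were lost, and that of Afp turned direction (0.46, adjusted p = 0.19). The 4 lists named here kept their direction and call, with adjusted p = 3.61e-05 for the unfolded protein response and 1.02e-18 for mitosis, both adjusted p. With uninfected cells as the baseline, lentiviral infection does not cancel, so these values include an infection effect and are no independent check. Most mitosis genes were lower in control shRNA than in parental cells, which by itself makes the mitosis difference more positive.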

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

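The tests of the signal range and of other splits of the arrays were planned, and so was the interaction count with parental cells as the baseline; all other tests of explanations in this part were chosen after the results were seen. The Merlin effect with the DCAF1 shRNA differed from that against control shRNA in 3734 genes, by a test of the difference itself. No group had Merlin with the control shRNA, so an effect of that hairpin is part of this contrast. Combined and Merlin cells differed in only 75 genes, so the contrast largely repeats the DCAF1 shRNA comparison with the sign turned. As log2 differences, Ly6g6d had 3.08, Egr1 2.97, Cd34 2.97, Nek8 2.90 and Cirbp 2.77, and Hspa1a had −5.22, Slc7a11 −4.11, Ptgs2 −3.32, Afp −3.08 and Frat2 −3.06. As medians of lists, mitosis had 0.81, Schwann lineage 0.97, adhesion 0.39, oxidative phosphorylation 0.25, the unfolded protein and amino acid response −0.97 and Nrf2 targets −0.80. With an estimated correlation only the unfolded protein list kept its call (adjusted p = 0.02), and adjusted p was 0.222 for mitosis, 0.0925 for Schwann lineage, 0.284 for adhesion, 0.271 for oxidative phosphorylation and 0.105 for Nrf2 targets, all adjusted p. Of 100 drawn splits of the 12 arrays 1, the real one, gave as many genes, and the highest other gave 1747. The other splits mix groups that differ in many genes, which changes both the contrast and the spread. They do not show what chance gives without an interaction, so nothing is concluded about chance from them. With parental cells as the baseline 5081 genes passed, with Hspa1a at −3.51, Slc7a11 at −2.95, Ptgs2 at −2.07, Ly6g6d at 3.34, Nek8 at 2.15, Cirbp at 2.01 and Egr1 at 1.81. Cd34 (0.24) and Frat2 (−1.77) lost the call, Afp reversed to 0.46, and the adhesion list lost its call (adjusted p = 0.087). Lentiviral infection does not cancel with that baseline, so these values include an infection effect. Of 1555 probe sets with no gene name, which no comparison used, 151 were higher and 226 lower than in control shRNA cells with Merlin, and 148 higher and 172 lower with the DCAF1 shRNA.

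Genes of the unfolded protein and amino acid response rose more with the DCAF1 shRNA alone than with Merlin added. In combined cells against control shRNA Slc7a11 (1.06) still rose, and 12 of 23 members of the unfolded protein list were higher, though the list was not called. The median of the unfolded protein and amino acid response list was −0.18 in combined against Merlin cells and 0.89 in DCAF1 shRNA against control shRNA cells. This cannot decide whether the hairpin has an effect that does not depend on Merlin. It would do so only if the hairpin was as active in the combined cells, which was not shown. Less lowering of Dcaf1 RNA in the combined cells stays open. Dcaf1 differed between combined and DCAF1 shRNA cells by −0.02 with an upper 95% bound of 0.11, but the lowering by the DCAF1 shRNA alone was itself only −0.201 against control shRNA (95% interval −0.326 to −0.077) and −0.062 against parental cells, so the bound does not lie under it. Combined arrays that were Merlin cells without the hairpin cannot be told apart from the label, because 1 Dcaf1 probe set was lower than in Merlin cells (−0.35, 95% interval −0.47 to −0.22) and the other had an upper bound of 0.25. An interaction of Merlin and DCAF1 in these genes, the biological explanation that the design gives, therefore stays a hypothesis.

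Merlin and the DCAF1 shRNA moved many genes the same way. The shared control shRNA arrays are argued against as the whole cause, because all 3 correlations without a shared array stayed above 0, with a lowest value of 0.23 over leaving out each array. Of 100 drawn splits of the 9 arrays 1, the real one, gave as many shared calls, 2982 against 2743 in the highest other split. The 2 highest other splits, 2743 and 2739, kept the 3 control shRNA arrays together and exchanged Merlin with DCAF1 shRNA arrays. The next, 1346, kept the 3 DCAF1 shRNA arrays together as the control. Every other drawn split mixed arrays of different groups, so nothing is concluded about chance from these counts. Part of the sharing may come from the control arrays, and a common effect of any change of vector was not separated from an effect of Merlin on the ligase.

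The arrays labelled Merlin-L64P stood apart in their signal range and in their genes. A compressed range is argued against as the cause of most of the gene calls. Quantile normalization, which removes an even compression, left 5335 changed genes, 101.8% of the 5243 in the values as deposited. The count covers all genes, so it does not test the calls of the brightest genes, where the range was lower. Little or no mutant transgene may explain the absence of an Nf2 excess over control shRNA, as the upper 95% bound of the change was 0.41 and wild type Merlin gave 1.31. It stays open, because the same probe set was 0.68 higher than in parental cells, and lower expression than in Merlin cells was not separated from none. The many genes that differ from control shRNA then have no tested cause.

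For the other counts the 6 arrays of a comparison make only 10 splits, too few for a share under 0.05, and the real split was the 1 with as many genes. Every other split mixes the groups compared, which differ in many genes except in combined against Merlin cells. Mixing shrinks the contrast and widens the spread, so the other counts do not show what chance gives. Nothing is concluded about chance from them. The real count and the highest other were 5483 and 4 for control shRNA against parental, 4997 and 4 for Merlin, 4653 and 2 for DCAF1 shRNA, 5335 and 3 for Merlin-L64P and 4789 and 2 for combined cells, each against control shRNA. They were 5667 and 1 for Merlin against Merlin-L64P, 3908 and 3 for combined against DCAF1 shRNA, 75 and 3 for combined against Merlin, and 4001 and 4 for Merlin against DCAF1 shRNA.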

How the results depend on the processing

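The alternatives without the arrays labelled Merlin-L64P, the gene lists with each array centred on its median, the interaction of named genes and lists against parental cells, and the pair of Merlin against control shRNA with DCAF1 shRNA against parental were chosen after seeing the data. Named genes kept direction and side of the threshold in 3538 of 3646 alternatives; 98 lost the call and 10 reversed. Without the Merlin-L64P arrays every count stayed within 1.5 times (4861 for Merlin, 61 for combined against Merlin, 2897 shared). The cause of the changes listed here was not tested, except where more probe sets or a stricter threshold set the count.

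With every probe set tested the counts were 8699 for control shRNA against parental, 7925 for Merlin, 7459 for DCAF1 shRNA, 8546 for Merlin-L64P, 7605 for combined cells, 8995 for Merlin against Merlin-L64P, 6184 for combined against DCAF1 shRNA, 6313 for Merlin against DCAF1 shRNA, 5874 for the interaction and 4725 shared. With a 2-fold minimum they were, in that order, 964, 681, 471, 841, 548, 1119, 388, 387, 653 and 222. Combined against Merlin gave 7 with that minimum, 34 with arrays centred on their medians, 19 at adjusted p of 0.01, and 1 with only the arrays compared. Against parental cells 4737 calls were shared and the correlation was 0.83. Both comparisons there use the same parental arrays, for which no unchanged groups were simulated, so part of this can come from them. Both also include lentiviral infection, and control shRNA against parental cells alone changed 5483 genes, so part can come from infection. The correlation of Merlin against parental with DCAF1 shRNA was 0.27 with a floor of 64. That of Merlin with DCAF1 shRNA against parental, 0.42, was 0.50 with that floor and 0.45 without the genes of lowest signal. Dcaf1 in DCAF1 shRNA cells was −0.114 with median centring, −0.034 with the mean of probe sets and −0.062 against parental cells.

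Lists called with an estimated correlation and by fry were 1 and 19 for control shRNA, 0 and 23 for Merlin, 1 and 22 for DCAF1 shRNA, 0 and 25 for Merlin-L64P, 0 and 20 for combined cells, 5 and 28 for Merlin against Merlin-L64P, 3 and 20 for combined against DCAF1 shRNA, 1 and 20 for Merlin against DCAF1 shRNA and 1 and 20 for the interaction; combined against Merlin had 3 with an estimated correlation. Merlin-L64P had 7 as deposited, 8 against parental and 7 with median centring, and the interaction had 10 against parental. Against parental cells these reversed: p53 targets (adjusted p = 0.821 for Merlin, 0.584 for DCAF1 shRNA), cholesterol (adjusted p = 6.66e-09, 1.05e-10, and 8.6e-09 for combined cells), Cxcl5 (0.430 with Merlin, 0.130 with Merlin-L64P, 0.608 combined), Ppargc1b (−0.387 combined), Afp (−1.542 with Merlin, −0.623 with DCAF1 shRNA, 0.461 in the interaction), Cyp51 (−0.604) and Sc5d (−0.297) with Merlin, and Chst15 (−1.377) with DCAF1 shRNA. With median centring ribosomal proteins (Merlin, adjusted p = 0.488) and oxidative phosphorylation (Merlin against Merlin-L64P, adjusted p = 0.919) reversed.

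Leaving out 1 array gave 5071 to 5159 for control shRNA, 4582 to 4703 for Merlin, 4231 to 4298 for DCAF1 shRNA, 4900 to 5015 for Merlin-L64P, 4294 to 4432 for combined cells, 5225 to 5401 for Merlin against Merlin-L64P, 3373 to 3514 for combined against DCAF1 shRNA, 3536 to 3789 for Merlin against DCAF1 shRNA, 3423 to 3668 for the interaction and 2671 to 2895 shared. Combined against Merlin gave 26 (without combined replicate 1), 42 (without combined replicate 3), 43 (without Merlin replicate 3) and 124 (without Merlin replicate 2). The correlations gave 0.60 to 0.64, 0.28 to 0.31, 0.23 to 0.25 and 0.39 to 0.42, Dcaf1 −0.249 to −0.155, losing its call in 3 of 6, and Nf2 −0.284 to −0.156.

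With median centring the median log2 change of all genes was −0.107 in control shRNA against parental, and the share of higher calls went from 51.4% to 33.3% (62.6% as deposited). That share went from 54.2% to 70.1% for Merlin (47.5% as deposited), 50.2% to 60.8% for DCAF1 shRNA (46.1%), 54.3% to 67.9% for combined cells (50.2%), 55.0% to 65.4% for Merlin against DCAF1 shRNA (51.5%) and 51.1% to 36.7% for the interaction (57.0%). Replicate numbers did not pair the arrays: 45 same-number pairs correlated at −0.06 to 0.07, and 4 of 18 arrays matched their own number best. With the replicate number as a block the counts were 4962 for Merlin, 4607 for DCAF1 shRNA, 77 for combined against Merlin and 3633 for the interaction, and no count moved by over 1.5 times. Values at the floor limit dim genes.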

Other observations

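The gene sets and tests in this part were chosen after the results were seen, and p is from limma's camera on the members whose values had not been looked at before, without adjustment. Heat shock genes rose as a set with the DCAF1 shRNA, 15 of 15 (median 0.74), among them the chaperone Hsph1 (1.80 ± 0.07), Hspa4l (1.79 ± 0.09), Hspa1b (1.60 ± 0.14) and the co-chaperone Dnajb1 (1.54 ± 0.05). For the 14 unseen members p was 1.71e-12, and 0.000523 with an estimated correlation. The set was chosen after Hspa1a was seen to rise and holds its near-identical neighbour Hspa1b, so p is no independent support. They rose with Merlin too, 14 of 15 (median 0.67), and with both vectors, 10 of 15 (median 0.46), and 14 of 15 had a negative interaction. That interaction largely repeats the rise with the DCAF1 shRNA with the sign turned, as combined against Merlin cells had a median of −0.11. In the arrays labelled Merlin-L64P the heat shock genes went the other way, with 10 of 15 lower and none higher (median −0.33), and in control shRNA against parental cells 5 rose and 5 fell. The cause was not tested.

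Genes that the ERK pathway switches on fell with Merlin, 13 of 15 (median −1.16), among them cyclin D1 (Ccnd1 −2.13 ± 0.07), the phosphatase Dusp6 (−1.69 ± 0.08), the feedback inhibitor Spry2 (−1.16 ± 0.08) and Etv5 (−1.50 ± 0.16). For the few unseen members, Spry1 (−0.33 ± 0.11), Spred1 (−0.60 ± 0.11) and Spred2, all lower, p was 0.00912. With the DCAF1 shRNA 10 of 15 fell and 1 rose (median −0.57). In combined cells 10 of 15 fell and none rose (median −0.96), in the arrays labelled Merlin-L64P 7 fell and 2 rose (median −0.58), and in control shRNA against parental cells 7 fell and 1 rose (median −0.28). For the unseen members p was 0.0113 with the DCAF1 shRNA, 0.0119 in combined cells, 0.126 in Merlin-L64P and 0.68 in control shRNA against parental cells. Tested directly, 10 of 15 were lower and 2 higher in Merlin than in Merlin-L64P cells (median −0.73), 8 were lower and 1 higher than in DCAF1 shRNA cells (median −0.25), and 10 of 15 had a positive interaction. That interaction largely repeats the fall with the DCAF1 shRNA with the sign turned, as combined against Merlin cells had a median of 0.21. For the unseen members p was 0.418 and 0.525 in the direct comparisons, so these rest on genes seen before. The cause was not tested.

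Targets of the FoxO transcription factors rose with Merlin, 13 of 18 against 1 that fell (median 0.52), among them Irs2, Bcl6 (1.47 ± 0.15), Fbxo32 (1.34 ± 0.22) and Foxo3 (1.24 ± 0.12), and Txnip fell (−0.62 ± 0.06). For 14 unseen members p was 6.57e-05. In the arrays labelled Merlin-L64P 7 of 18 rose and 9 fell (median −0.15). In control shRNA against parental cells 16 of 18 rose (median 0.82). With the DCAF1 shRNA 8 of 18 rose and 1 fell (median 0.30), and in combined cells 13 rose and 1 fell (median 0.37). Tested directly, 9 were higher and 2 lower in Merlin than in Merlin-L64P cells, and 8 were higher and none lower than in DCAF1 shRNA cells. For the unseen members p was 0.068 against Merlin-L64P (0.162 with an estimated correlation) and 0.00058 against DCAF1 shRNA (0.0158). The difference from Merlin-L64P thus did not pass in the unseen members.

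Clock output genes rose in the arrays labelled Merlin-L64P, 8 of 9 (median 0.80): Dbp, Nr1d1 (2.46 ± 0.10), Per1 (2.18 ± 0.15) and Per2 (1.23 ± 0.26). They rose in part with Merlin too, 5 of 9 (median 0.54), and in combined cells, 4 of 9 (median 0.38). With the DCAF1 shRNA 3 of 9 rose (median 0.30), and in control shRNA against parental cells 4 of 9 (median 0.20), with none lower. For the unseen members p was 0.128 and 0.0177 in that order, and 0.264 and 0.0928 with an estimated correlation. Tested directly, 7 of 9 were lower in Merlin than in Merlin-L64P cells and none higher (median −0.56), so the rise was larger in Merlin-L64P. For the unseen members of that comparison p was 0.00898, but 0.0673 with an estimated correlation. A shift of clock phase at harvest was to be tested by the genes of opposite phase, whose median was 0.21 over 3 genes. That test is void, because Npas2 was at the floor in both groups and could not fall. With only Clock (0.78 ± 0.10) and Arntl (0.21 ± 0.14) left, nothing is concluded about phase.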
